A study of Mus musculus with 17 samples.

How the data were processed

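RNA was measured by sequencing in 17 libraries of mouse cells that carry the R172H allele of p53. Per the labels' protocols, total RNA was fragmented and reverse transcribed, adapters were ligated, and barcoded libraries were read as single-end reads of 60 bases. Per the submitters' processing notes, the tools used upstream were cutadapt, TopHat2 2.0.10, HTSeq 0.6.1p1 and DESeq2 1.6.3, and the genome build was mm10. The role and order of these tools, the gene annotation and the strand setting of the counting are not given in the sources used here. The deposited table holds whole-number counts per gene symbol, not normalized, for 23420 genes. In the table, 4 columns match no sample of the series and were used in no step.

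Libraries were assigned to groups from their titles. There were libraries of 3 samples of bone marrow mesenchymal stem cells (MSC), 6 first-generation tumour lines (TL1), 4 second-generation tumour lines (TL2), 2 control clones of tumour line cells (Mut clone) and 2 clones labelled as p53 knockout (KO clone). A number in parentheses in the titles of MSC, TL1 and TL2 libraries was kept as part of the library name, with a letter where a group holds the number more than once. Per the labels' protocols, tumour-derived cells grew on agar-coated plates with leukaemia inhibitory factor (LIF) and MSC cultures in MSC medium, so culture conditions and the comparison of tumour lines with MSC coincide. The labels do not say that libraries of a group came from separate animals or cultures. The p-values therefore measure the spread between these libraries, which may be technical in part. Library totals ranged from 12215025 to 15962341 counts. A chi-square of the counts of each pair of libraries in a group, over genes with a summed count of at least 20, found no pair that differed by as little as sampling noise.

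Values per library are CPM, counts relative to a common total, on library sizes scaled by the trimmed mean of M values (TMM), computed from the deposited counts. Differences were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, after filtering by expression, with robust estimation and Benjamini-Hochberg adjustment, and genes with an adjusted p under 0.05 were called. The comparison of tumour lines with MSC took the mean of TL1 and TL2 minus MSC in a fit of the 13 libraries, and the same fit gave TL2 minus TL1. The clones were fitted alone, KO minus Mut. In all, 3 comparisons of this kind were made. Log2 changes are given with their standard error (SE). A change against a group with no counts is a lower bound computed with 3 counts over the group, and a group with 1 to 3 counts is given as a ratio with a 95% counting interval. Such bounds and intervals cover counting error only.

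A set of 29 gene lists was fixed before the data were examined. They cover pluripotency, mesenchymal stromal, osteogenic, adipogenic, chondrogenic, macrophage and haematopoietic, endothelial, epithelial, smooth muscle and contractile, fibrillar matrix, matrix protease, epithelial-mesenchymal transition (EMT), cell cycle, p53 target, mevalonate, glycolysis and hypoxia, interferon, antigen presentation, inflammatory cytokine, cancer stem cell, LIF and STAT3 target, ribosome biogenesis, germline, Hox, imprinted growth, WNT, apoptosis and autophagy, immediate early, and oxidative stress and unfolded protein response genes. All 759 listed genes had an entry in the table, 5 of them under an older symbol. Lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, each adjusted over the 29 lists. Genes called within a list are also counted after adjustment over the list alone.

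The genes named in the text follow a rule fixed before the data were examined. It takes Trp53, the 10 genes with the largest change in each direction among called genes with a mean of at least 10 CPM in the higher group and no overlap between the libraries of the groups, up to 4 called members of each list, 10 fixed genes, and the 5 genes called most clearly in opposite directions by both comparisons. Predicted and clone-named genes were left out. Genes named outside the rule are said to be so. Some genes that the rule takes are not reported here, though counts over lists and over named genes include them. Gene positions are 1-based and come from a RefSeq gene table of GRCm38.p6, which matches the build named in the submitters' notes; 23259 of the symbols matched it, 1688 of them through a synonym. Without a stated strand setting, reads of a gene and of an antisense or overlapping partner cannot be told apart, which concerns Igf2, H19, Peg3 and other imprinted genes in particular.

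The numbers in parentheses were checked for pairing before calls were compared. Deviations of TL1 and TL2 libraries from their group means correlated across genes within a number at r = 0.472, 0.374 and 0.484 for the numbers 1, 2 and 3, so the numbers were taken to pair TL1 with TL2, and the fit with the number as a block was made beside the one without. The pairing rests on these correlations, since the labels do not say what a number marks. For the number 3 the lines differed. TL2 3 correlated in log2 CPM with TL1 3b at 0.945 and with TL1 3a at 0.848, its lowest value with any tumour line.

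The test was checked on simulated counts with 200 changed genes per comparison. All genes and groups had the same dispersion, 0.3 in the comparisons of tumour lines and 0.08 in that of clones. Libraries were drawn independently, and only genes with a mean of at least 100 counts were changed. The real spread differed between groups and many genes had fewer counts, so the shares below hold for these settings and not for the real fits. In the simulated comparison of tumour lines with MSC, over 13128 genes, 1.47% of genes changed by 1 on the log2 scale were recovered, 56.1% of those changed by 2 and 100% of those changed by 4. In the simulated comparison of TL2 with TL1, over 13073 genes, the shares were 2.94%, 60.6% and 100%. In the simulated comparison of clones, over 12109 genes, they were 10.3%, 92.4% and 100%. In each, 3 unchanged genes were called. Alternatives covered the scaling (DESeq2 size factors, library totals), the filter, the test (DESeq2 1.42.0, limma-voom), the libraries in the fit, the threshold, the block, and each library left out in turn. Fits without Rn45s, a ribosomal precursor RNA, a fit of the 10 tumour lines alone, and list tests with the block by an estimated correlation and by fry were added after the data were seen.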

Results

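The libraries came from bone marrow mesenchymal stem cells (MSC) of knock-in mice carrying R172H p53, a mutant form of the tumour suppressor p53, from tumour lines that arose from such cells, and from clones of tumour line cells with and without knockout of the mutant gene. The series describes the tumour lines as resembling cancer stem cells. There were libraries of 3 MSC samples, 6 first-generation tumour lines (TL1), 4 second-generation tumour lines (TL2), 2 control clones (Mut clones) and 2 knockout clones (KO clones). Total counts ranged from 12643520 to 13783786 in MSC, 12540701 to 14574984 in TL1, 13901362 to 15962341 in TL2, 12215025 to 13661846 in Mut clones and 13321954 to 13580595 in KO clones. Correlations of log2 CPM between libraries of a group were 0.965 to 0.974 in MSC, 0.845 to 0.959 in TL1, 0.871 to 0.955 in TL2, 0.974 for the Mut clones and 0.968 for the KO clones. Rn45s, a precursor of ribosomal RNA, took 4.14% of the counts of KO clone 2 and between 0.476% and 1.59% in the other libraries. Xist, the RNA of the inactive X chromosome, was counted at 247 to 907 CPM in all 17 libraries, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had at most 2 counts each in any library.

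The comparison of tumour lines with MSC asked how lines derived from tumours differ from the cells they arose from. In the tumour lines, the lists of fat lineage, Hox and imprinted growth genes were lower, though 4, 8 and 5 of their tested genes had positive changes. The matrix and contractile lists were lower by camera at the preset correlation, calls that were lost with an estimated correlation (adjusted p = 0.0905 and 0.0678). Lpl, the lipase that releases fatty acids from lipoproteins, fell by 8.14 on the log2 scale (SE 0.679), from 460 ± 184 CPM (SD, n = 3) to 1.64 ± 1.77 CPM (n = 10). Pitx1, a homeobox factor of hindlimb identity, fell by 9.85 (SE 0.463), from 61.3 ± 11.4 to 0.0540 ± 0.0417 CPM, and Aldh1a2, which makes retinoic acid, fell by 9.79 (SE 0.969). Aqp5, a water channel, rose by 8.95 (SE 1.69), from 0.186 ± 0.123 to 108 ± 97.5 CPM. Of 13262 genes tested, edgeR called 512 higher and 635 lower in tumour lines, and 3507 had an unadjusted p under 0.05. This fit treats the 10 tumour lines as independent, though TL1 and TL2 lines of a number resembled each other. With the tumour lines summed per number, 551 higher and 619 lower genes were called, among them 354 of the 512 and 471 of the 635. Scaling by library totals alone gave 680 higher and 547 lower. The libraries of both sides did not overlap for 1666 genes, 12.6% of those tested against 0.699% by chance, and 996 of the called genes were among them. Fits without MSC 1, MSC 2 or MSC 3 called 88 and 261, 247 and 440, and 75 and 229 genes higher and lower.

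Among the genes with the largest increases, each higher in all 10 tumour lines than in all 3 MSC libraries, were Aqp5 (chromosome 15, 99591028 to 99594829; adjusted p = 0.00749), Dynap (log2 change 8.08, SE 1.55), Fmnl1 (7.25, SE 1.04), a formin that builds actin filaments, and Dock8 (6.20, SE 1.54), an exchange factor for small GTPases. Slc9a2, a sodium-proton exchanger, had 2 counts over the MSC libraries and a ratio of 194 (95% counting interval 53.6 to 1599). Il33, an alarmin cytokine, rose by 5.63 (SE 1.52), Pla2g7 by 5.62 (SE 1.27), Fam83g by 5.32 (SE 0.864), Inpp4b, an inositol phosphatase, by 5.16 (SE 1.39) and Igfbp6, which binds insulin-like growth factors, by 5.11 (SE 0.757). Among the largest decreases, Pitx1 (chromosome 13, 55825044 to 55836190) had the smallest adjusted p, 3.25e-07. Dscam, a neuronal adhesion molecule, had no count in any tumour line and was at least 556-fold lower. Also lower were Svep1 (log2 change -9.37, SE 0.684), Srpx (-9.25, SE 0.763), Adam23 (-9.21, SE 0.862), Pamr1 (-8.87, SE 1.18), Eya2, a transcriptional cofactor (-8.74, SE 0.949), and Fbn2, a microfibril protein (-8.70, SE 1.04). Rps4y2 fell by 9.27 (SE 0.593); it is a close copy of Rps4x, and counting could split reads between them, so its level is uncertain.

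**Figure D1:**
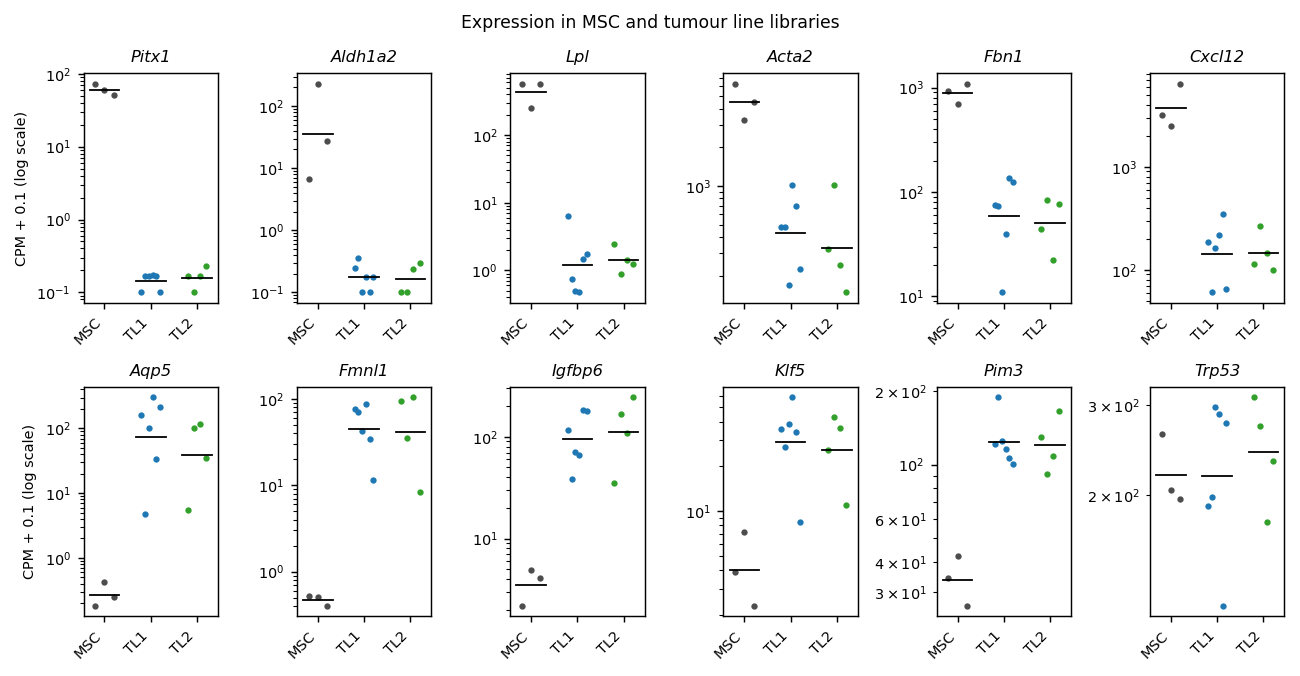
Expression of 12 genes in each MSC, TL1 and TL2 library, with CPM plus 0.1 on a log axis; each dot is 1 library and each line the geometric mean of a group. Pitx1, Aldh1a2, Lpl, Acta2, Fbn1 and Cxcl12 lie lower in every tumour line than in every MSC library, Aqp5, Fmnl1, Igfbp6, Klf5 and Pim3 lie higher, and Trp53 overlaps between the groups.

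In the adipogenic list, 7 of 14 tested genes fell and 0 rose, with 7 and 0 adjusted over the list alone. Beside Lpl these included Fabp4, a fatty acid carrier (log2 change -4.89, SE 0.728), Plin4, which coats lipid droplets (-4.36, SE 0.516), and Adipoq, the adipokine adiponectin (-5.08, SE 0.805), the last at only 1.85 ± 1.26 CPM in MSC. The list was lower by camera (adjusted p = 4.06e-07) and with an estimated correlation (adjusted p = 0.0261). Of the 25 tested Hox genes and cofactors, 6 fell and 0 rose (8 and 0 adjusted over the list alone; adjusted p = 2.34e-05 by camera and 0.0112 with an estimated correlation). Hoxb2 had no count in a tumour line and was at least 314-fold lower, Hoxb3 had 1 count and a ratio of 1136 (counting interval 204 to 44887), and Hoxa5 fell by 1.43 (SE 0.250). Of 18 imprinted growth genes, 5 fell and 0 rose (8 and 0 adjusted over the list alone; adjusted p = 3.19e-06 and 0.0112 with an estimated correlation). The lower genes included Ndn (-8.31, SE 1.03), Dio3, which inactivates thyroid hormone (-6.05, SE 0.974), the amino acid transporter Slc38a4 (-5.15, SE 1.08), and Nnat (-3.19, SE 0.547).

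Of 34 fibrillar matrix genes, 10 fell and 0 rose (22 and 1 adjusted over the list alone). Fbn1, the main microfibril protein, fell from 906 ± 196 to 68.2 ± 40.4 CPM (log2 change -3.76, SE 0.513), with Lox, which crosslinks collagen (-2.77, SE 0.472), Col6a2 (-3.98, SE 0.705) and Col15a1 (-7.20, SE 0.832) also lower. The camera call (adjusted p = 1.36e-16) was lost with an estimated correlation (adjusted p = 0.0905). Of 17 smooth muscle and contractile genes, 6 fell and 0 rose (12 and 0 adjusted over the list alone), among them Acta2, smooth muscle actin (-3.29, SE 0.524), Tagln (-3.71, SE 0.636) and Cald1 (-1.18, SE 0.184), with adjusted p = 2.84e-10 by camera and 0.0678 with an estimated correlation. Of 10 chondrogenic genes, 2 fell, the cartilage collagens Col2a1 (-7.97, SE 0.842) and Col11a1 (-7.22, SE 1.06) (3 adjusted over the list alone; adjusted p = 0.00148 by camera and 0.121 with an estimated correlation). Of 14 osteogenic genes, 3 fell and 1 rose (7 and 2 adjusted over the list alone), the bone matrix gene Ibsp (-7.67, SE 1.16), the osteoblast factor Sp7 (-4.36, SE 1.07) and Omd (-1.92, SE 0.539), while Phex, an endopeptidase, rose by 3.98 (SE 0.706); adjusted p = 0.0202 by camera and 0.417 with an estimated correlation.

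Of 24 mesenchymal stromal markers, 4 fell and 0 rose (8 and 2 adjusted over the list alone). Cxcl12, the chemokine that retains blood stem cells in marrow, fell from 4029 ± 2076 to 166 ± 90.7 CPM (log2 change -4.59, SE 0.463), with Thy1 (-6.78, SE 0.986), the endoglin gene Eng (-3.95, SE 0.612) and Itgav (-0.99, SE 0.269). The median of this list was 0.15, and the camera call in the lower direction (adjusted p = 0.0249) was lost with an estimated correlation (adjusted p = 0.375). Of 22 matrix protease genes, 2 fell (3 lower and 1 higher adjusted over the list alone), Adamts1 and the inhibitor Timp3; adjusted p = 0.0154 by camera and 0.373 with an estimated correlation. Of 16 EMT factors, 3 fell (6 adjusted over the list alone), among them the cadherin Cdh11 (-5.32, SE 1.02) and Snai2 (-1.09, SE 0.309); adjusted p = 0.00229 and 0.223 with an estimated correlation. Of 22 WNT genes, 5 fell and 1 rose (7 and 3 adjusted over the list alone), with the WNT inhibitor Sfrp1 (-7.67, SE 0.855), the receptor Lgr5 (-6.29, SE 0.850) and Nkd2 (-4.47, SE 0.796) lower and the transcription factor Tcf7 (2.47, SE 0.354) higher; adjusted p = 0.0150 and 0.417 with an estimated correlation. Of 30 glycolysis and hypoxia genes, 5 fell and 1 rose (8 and 1 adjusted over the list alone), Higd1a, P4ha2 and Pfkl among the lower and Ndrg1 the higher; adjusted p = 0.00148 and 0.470 with an estimated correlation. Of 14 antigen presentation genes, 2 immunoproteasome subunits, Psmb8 (-3.45, SE 0.807) and Psmb9 (-3.07, SE 0.875), fell (3 adjusted over the list alone). The list had adjusted p = 0.00332 by camera and 0.417 with an estimated correlation. Its median log2 difference from the median library was 0.12, 1.65 and 1.29 in MSC 1, MSC 2 and MSC 3, and -1.09 to 1.04 in the tumour lines.

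Of 20 LIF and STAT3 targets, 5 rose and 2 fell (6 and 2 adjusted over the list alone). The kinase genes Pim3 (log2 change 1.90, SE 0.253) and Pim1 (1.75, SE 0.330), Ier3 (1.61, SE 0.351) and Junb (1.59, SE 0.356) were higher in tumour lines, whose medium contained LIF. The camera call (adjusted p = 0.0462) was lost with an estimated correlation (adjusted p = 0.470) and with the number as a block (adjusted p = 0.0935). The median gene of this list lay 1.06 above the median library on the log2 scale in TL1 3a. It lay between -0.19 and 0.34 in the other tumour lines, beside -0.16, -0.05 and 0.07 in MSC. For the cell cycle list, 0 of 46 genes were called by edgeR and 45 had a positive change, with adjusted p = 0.0111 by camera and 0.707 with an estimated correlation. Not all lines followed this direction: the median gene of the list lay 1.28 below the median library on the log2 scale in TL1 3a, lower than in any MSC library, and 0.81 below in TL2 3, beside -0.15, 0.00 and -0.98 in MSC. For ribosome biogenesis, 0 of 32 were called and 29 were positive, with adjusted p = 0.0302 by camera and 0.707 with an estimated correlation, and TL1 3a, at -1.17, again lay below all MSC libraries.

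The other lists were not called by camera. By fry, which called 14 of the 29 lists, pluripotency genes (adjusted p = 0.0184) and apoptosis genes (0.0184) were higher and cancer stem cell markers (0.0490) lower. Cell cycle, ribosome biogenesis, LIF and STAT3, glycolysis and hypoxia, and antigen presentation genes, called by camera, were not called by fry. By camera with an estimated correlation, pluripotency, apoptosis and cancer stem cell lists had adjusted p = 0.373, 0.373 and 0.417. Of 40 p53 targets, 4 rose and 2 fell (5 and 3 adjusted over the list alone), with Eda2r (4.63, SE 0.778), Pmaip1 (2.26, SE 0.575) and the kinase gene Plk3 (2.10, SE 0.461) higher and the death receptor gene Tnfrsf10b (-0.86, SE 0.229) lower. Of 15 pluripotency genes, Klf5 rose by 2.88 (SE 0.613), 1 called (5 higher and 1 lower adjusted over the list alone). Of 18 macrophage and haematopoietic markers, Cd14 rose and Fcer1g fell, the latter at 2.71 ± 1.43 CPM in MSC (1 and 1 adjusted over the list alone). Of 6 endothelial markers, 1, Eng, fell. Of 11 epithelial markers, edgeR called 0 (5 higher and 1 lower adjusted over the list alone). Of 18 inflammatory cytokine genes, Il33 and Ccl8 rose and Ccl9 fell; Ccl8 had 3 counts over the MSC libraries and a ratio of 27.1 (counting interval 9.28 to 132). Of 23 cancer stem cell markers, 4 fell and 0 rose (4 and 1 adjusted over the list alone), Aldh1a2, Lgr5, Aldh1a1 and the receptor Kit, the last with 1 count over the tumour lines and a ratio of 442 (counting interval 79.4 to 17472). Of 20 apoptosis genes, 2 rose, among them Casp4 (2.28, SE 0.624), and 3 adjusted over the list alone. Of 23 oxidative stress and unfolded protein response genes, Nqo1 (2.31, SE 0.552) and Gclm (1.11, SE 0.278) rose, with 2 higher and 1 lower adjusted over the list alone. Of 20 immediate early genes, Junb rose and Zfp36 fell (2 higher and 1 lower adjusted over the list alone). No gene of 25 mevalonate, 35 interferon or 5 germline genes was called, with 1 germline gene lower adjusted over the list alone. The median and the direction of the test had opposite signs for macrophage, endothelial, inflammatory cytokine, cancer stem cell and germline genes, none of which was called as a list by camera.

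Among the fixed genes, Trp53 differed by 0.14 (SE 0.259; adjusted p = 0.755), with 221 ± 36.2 CPM in MSC and 237 ± 62.5 CPM in tumour lines. Sox2, a pluripotency factor, had 1 count over the MSC libraries, a mean of 19.4 ± 26.6 CPM in tumour lines and adjusted p = 0.0579. Cdkn1a, the cell cycle inhibitor p21, had a log2 change of 2.38 (SE 0.689) and adjusted p = 0.0504. Myc (adjusted p = 0.411), Klf4 (0.797), Nanog (0.468), Mdm2 (0.441), Cdkn2a (0.779) and Csf1r (0.993) were not called either. Pou5f1 and Ptprc had too few counts to be tested.

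**Figure D2:**
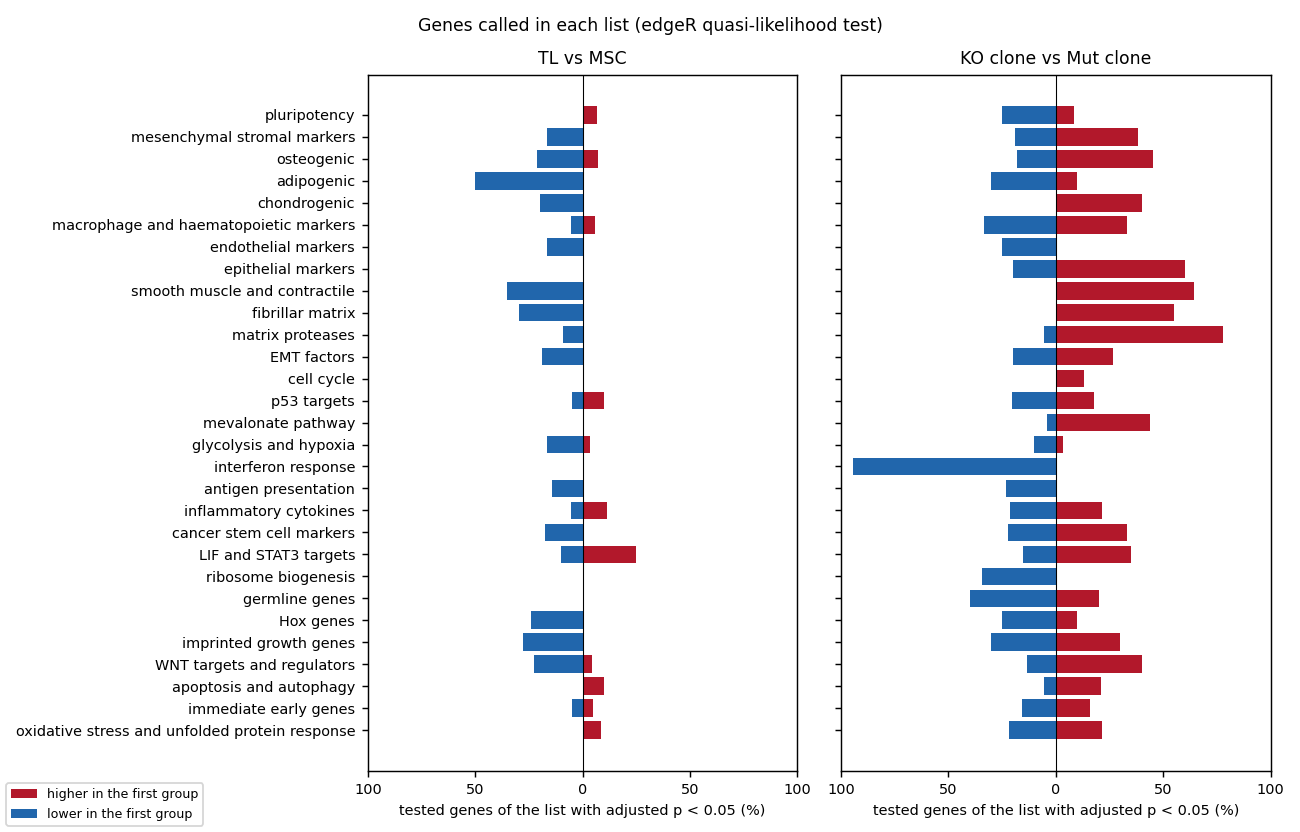
Share of the tested genes of each of the 29 lists that were called higher (red, to the right) or lower (blue, to the left), in percent, for tumour lines against MSC and for KO clones against Mut clones. For the clones the interferon list reaches farthest, with 33 of 35 genes lower.

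The comparison of TL2 with TL1 asked whether the lines of the second generation differ from those of the first. No gene passed the threshold in edgeR (0 of 13262; 246 at an unadjusted p under 0.05, where 663 are expected by chance). limma-voom also called 0, and DESeq2 called 3, all lower in TL2. These genes, chosen after their values were seen, were Klhl13 (0.117 CPM in TL2), the neurotrophin receptor gene Ngfr (1.27 against 18.8 CPM) and Pnmal2 (0.149 against 15.7 CPM). Klhl13, Ngfr and Pnmal2 were highest in TL1 3a, at 40.3, 54.6 and 57.3 CPM. Fits with the number as a block also called 0 genes.

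Among the lists, the genes of sterol synthesis were higher in TL2 by camera at the preset correlation, a call lost with an estimated correlation (adjusted p = 0.710). In the mevalonate list 24 of 25 genes had a positive change (median 0.44; camera adjusted p = 7.35e-15), and in the cell cycle list 42 of 46 did (median 0.25; adjusted p = 5.90e-05). The matrix proteases had a median of -0.38 (adjusted p = 0.0418). All 3 calls were lost with an estimated correlation (adjusted p = 0.710 for each) and by fry (0.895 for each), and 0 members were called by edgeR. With the number as a block, which pairs TL1 with TL2, camera also called epithelial markers (adjusted p = 0.0210), inflammatory cytokines (0.0210) and cancer stem cell markers (0.0332), all lower; these calls too were lost with an estimated correlation in that fit (adjusted p = 0.331 for each) and by fry (0.886 for each). TL1 2a, in which the median mevalonate gene lay 1.71 below the median library on the log2 scale, stood apart from the other lines in the mevalonate list, and for the cell cycle list TL1 3a was lowest at -1.28, with TL2 3 next among the lines at -0.81. Trp53 was at 229 ± 69.9 CPM in TL1 (n = 6) and 249 ± 57.3 CPM in TL2 (n = 4). Cdkn1a was at 155 ± 120 and 58.2 ± 19.8 CPM, Myc at 248 ± 187 and 375 ± 447 CPM, and Sox2 at 15.5 ± 19.3 and 25.1 ± 37.9 CPM, none called.

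The comparison of clones asked what changes when mutant p53 is removed. Trp53 (chromosome 11, 69580348 to 69591873) was at 80.8 and 89.6 CPM in the KO clones, 358 and 280 CPM in the Mut clones, 197 to 263 CPM in MSC and 122 to 311 CPM in the tumour lines. It was lower in both KO clones, by 1.89 on the log2 scale (SE 0.226; adjusted p = 0.00259). In the KO clones, contractile and extracellular matrix genes rose and interferon-stimulated genes fell, at the preset correlation between genes; these calls were lost with an estimated correlation (adjusted p = 0.743, 0.359 and 0.743). Myf5, a muscle-determining factor without a count in the Mut clones, was at 75.1 ± 20.0 CPM (SD, n = 2), at least 660-fold higher, and Igf2, a fetal growth factor, rose by 13.28 (SE 0.437) to 1596 ± 112 CPM. Isg15, an interferon-induced ubiquitin-like modifier, fell from 355 ± 192 to 2.73 ± 0.303 CPM, and Myc, the growth-promoting transcription factor, fell by 3.76 (SE 0.222), from 1874 ± 159 to 137 ± 0.734 CPM. In the tumour lines, which kept the mutant gene, Myf5 ranged from 0 to 197 CPM and Igf2 from 0.259 to 1725 CPM. Isg15 ranged from 6.89 to 383 CPM and Myc from 94.9 to 1042 CPM in the same lines. Of 12238 genes tested, edgeR called 1734 higher and 1466 lower. Fits without Mut clone 1, Mut clone 2, KO clone 1 or KO clone 2 called 1002 and 753, 796 and 551, 1016 and 632, and 873 and 502, and a fit of all 17 libraries 512 and 308. The libraries did not overlap for 8525 genes, 69.7% against 33.3% by chance. Scaling by library totals alone moved the median of all genes from 0.00 to -0.13 and gave 1472 higher and 1816 lower.

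The clones differed from each other also in the tumour lines they resembled. Both Mut clones correlated best with TL2 3 (r = 0.960 and 0.951 across genes, which are not independent replicates), and both KO clones with TL1 2b (0.922 and 0.925). The titles label all of the clones as first generation. Among first-generation lines, the Mut clones correlated best with TL1 3b (r = 0.929 and 0.918) and least with TL1 3a (0.812 for both). The labels give no tumour line of origin for the clones. Single genes did not all follow these correlations. Igf2 was at 1517 and 1675 CPM in the KO clones and 0.259 to 0.868 CPM in the lines numbered 2. Peg3 was at 134 and 110 against 0 to 0.420 CPM. H19, chosen after its values were seen, was at 0.708 and 0.876 against 226 to 5019 CPM. The lines numbered 1 and TL1 3a had Igf2 at 109 CPM or more, Peg3 at 26.8 CPM or more and H19 at most 0.674 CPM.

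Among the largest increases were Lrrn1 (chromosome 6, 107529726 to 107570228), at least 5630-fold higher, Tmem8c, the muscle fusion protein myomaker, at least 1536-fold, the imprinted gene Peg3, at least 1069-fold, Cap2 at least 1075-fold, Cpne4 at least 884-fold, the RNA-binding protein gene Rbm24 at least 762-fold and Bves at least 563-fold. None of these had a count in a Mut clone, and all were at 0.129 CPM or lower in TL2 3, which kept the mutant gene. Peg3 and Bves in the KO clones lay inside the range of the tumour lines (0 to 399 and 0.0643 to 133 CPM). The other genes lay above that range in the KO clones, with at most 80.9 CPM in a tumour line for Lrrn1 and 60.2 CPM for Tmem8c. Among the largest decreases, Kcnab2, a potassium channel subunit, was at least 1825-fold lower, Oas2, an interferon-induced synthetase, at least 286-fold, Lipo1 at least 205-fold, Hmgcll1 at least 166-fold, the chemokine Cxcl11 at least 131-fold, Tdrd9, which silences transposons in germ cells, at least 118-fold and Slc4a8 at least 106-fold. Hdgfrp3, Ror2 and Col4a5 had 1 to 3 counts over the KO clones, with ratios of 1611 (counting interval 289 to 63624), 1548 (278 to 61135) and 1366 (467 to 6623). The lower genes also varied widely among the tumour lines. Kcnab2 ranged from 0 to 153 CPM there, Oas2 from 0 to 61.3 CPM, Lipo1 from 0 to 25.7 CPM and Col4a5 from 0.0650 to 150 CPM.

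Of 35 interferon response genes, 33 fell and 0 rose (35 and 0 adjusted over the list alone), among them Cxcl10 (-6.48, SE 0.394), Ddx58, a sensor of viral RNA (-4.32, SE 0.421), and Irf9 (-3.20, SE 0.309). The camera call (adjusted p = 3.71e-28) was lost with an estimated correlation (adjusted p = 0.743). The level of this list, as the median log2 difference from the median library, was 3.88 and 2.01 in the Mut clones and -2.73 and -2.43 in the KO clones, and it ranged from -1.55 in TL1 1a to 2.77 in TL1 2a and 3.85 in TL2 3, which kept the mutant gene. Of 13 antigen presentation genes, 3 fell (3 adjusted over the list alone), B2m, H2-D1 and H2-T23 (adjusted p = 0.00772 and 0.772 with an estimated correlation). The level of this list was 2.23 in Mut clone 1 but -0.06 in Mut clone 2, beside -1.15 and -1.03 in the KO clones.

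Of 14 smooth muscle and contractile genes, 9 rose and 0 fell (11 and 0 adjusted over the list alone), among them Des, the muscle filament desmin (11.20, SE 0.911), Synpo2 (6.20, SE 0.296), Tpm2 (2.13, SE 0.358) and Vcl (1.63, SE 0.290); adjusted p = 3.08e-06 by camera and 0.743 with an estimated correlation. Des was below 1 CPM in TL2 3 and the Mut clones and at 53.6 to 1538 CPM in the other tumour lines. Genes of skeletal muscle, chosen after their values were seen, were called higher in the KO clones as well: Acta1 (11.37, SE 0.389), Cdh15 (12.25, SE 0.385), Myod1 (330 ± 3.21 CPM), Myog (208 ± 41.7 CPM) and Myh3 (257 ± 46.2 CPM), the last 3 below 0.2 CPM in the Mut clones. Of 29 fibrillar matrix genes, 16 rose and 0 fell (16 and 2 adjusted over the list alone). The matricellular genes Postn (10.84, SE 0.481) and Tnc (5.52, SE 0.254) and the collagens Col12a1 (6.82, SE 0.330) and Col5a1 (3.47, SE 0.215) were among them; adjusted p = 7.02e-10 and 0.359 with an estimated correlation. Of 18 matrix protease genes, 14 rose and 1 fell (14 and 2 adjusted over the list alone), with Plau, the urokinase gene (3.91, SE 0.265), and Adamts2 (5.49, SE 0.539); adjusted p = 9.16e-09 and 0.359 with an estimated correlation.

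Of 46 cell cycle genes, 6 rose (1 adjusted over the list alone), with Rrm2, a subunit of ribonucleotide reductase (2.24, SE 0.212), E2f8 (1.64, SE 0.341), Mcm5 (1.52, SE 0.357) and Foxm1 (1.01, SE 0.267). The list had adjusted p = 0.0219 by camera and 0.835 with an estimated correlation. Its level was 0.22 in Mut clone 1 and -0.59 in Mut clone 2, beside 0.46 and 0.42 in the KO clones. Of 25 mevalonate genes, 11 rose and 1 fell (11 and 1 adjusted over the list alone), and Cyp51 rose by 1.47 (SE 0.195). The camera call was lost with an estimated correlation (adjusted p = 0.772). The level of the mevalonate list was -0.18 in Mut clone 1 and -0.95 in Mut clone 2, beside 0.41 and 0.64 in the KO clones. Of 32 ribosome biogenesis genes, 11 fell and 0 rose (13 and 1 adjusted over the list alone), among them Odc1, which starts polyamine synthesis (-1.85, SE 0.239), Wdr12 (-1.46, SE 0.222), Rrs1 (-1.23, SE 0.230) and Dkc1 (-0.98, SE 0.206); adjusted p = 0.00761 and 0.743 with an estimated correlation. KO clone 2 held 4.14% of Rn45s beside 0.878% in KO clone 1. None of the 8 lists called at the preset correlation was called by fry.

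Of 39 p53 targets, 7 rose and 8 fell (9 and 11 adjusted over the list alone). Cdkn1a rose by 3.53 (SE 0.239), from 12.7 ± 1.21 to 145 ± 15.3 CPM, and Gdf15, a stress cytokine without a count in the Mut clones, was at least 229-fold higher. Across the tumour lines, which kept the mutant gene, Cdkn1a ranged from 34.4 to 312 CPM. The KO clones lay inside this range and the Mut clones, at 11.8 and 13.5 CPM, below it. Bbc3, which promotes apoptosis, fell by 2.51 (SE 0.310) and Sesn2 by 1.81 (SE 0.228), and Mdm2 did not pass the test (adjusted p = 0.608). Cdkn2a fell by 1.08 (SE 0.229). Sox2 had 2 counts over the KO clones against 30.1 ± 4.83 CPM, a ratio of 380 (counting interval 105 to 3137), and Klf4 fell by 3.40 (SE 0.493) and Klf2 by 2.45 (SE 0.344). Of 12 pluripotency genes, 1 rose and 3 fell, and Nanog was not called (adjusted p = 0.613). Of 19 apoptosis genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone). The caspase inhibitors Birc2 (3.37, SE 0.441) and Birc3 (1.82, SE 0.345) rose; they neighbour each other on chromosome 9 and were high also in the tumour lines numbered 2, where Birc2 was at 184 to 242 CPM beside 13.6 and 12.6 CPM in the Mut clones.

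Birc2 and Birc3 lie in a run of 12 genes on chromosome 9 (4294793 to 8042875), described here after its values were seen, which also holds Yap1, a transcriptional coactivator of the Hippo pathway. The median gene of the run lay 2.17 and 1.30 above the median library on the log2 scale in the KO clones, and -0.42 and -0.61 in the Mut clones. It lay 2.84 to 3.43 above in the 4 tumour lines numbered 2, 2.03 above in TL1 1a, and -0.20 to -0.43 in MSC. The raised stretch was not the same in all of these libraries: Aasdhppt, Kbtbd3 and Msantd4, at its start, lay between -0.52 and 0.34 in the KO clones and between 0.44 and 0.64 in TL1 1a, against 2.88 to 4.25 in the lines numbered 2, and Casp4 was at 7.48 and 1.20 CPM in the KO clones beside 8.84 and 10.1 CPM in the Mut clones. Yap1 was at 2261 and 1335 CPM in the KO clones, 150 and 120 CPM in the Mut clones and 172 to 205 CPM in MSC.

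**Figure D3:**
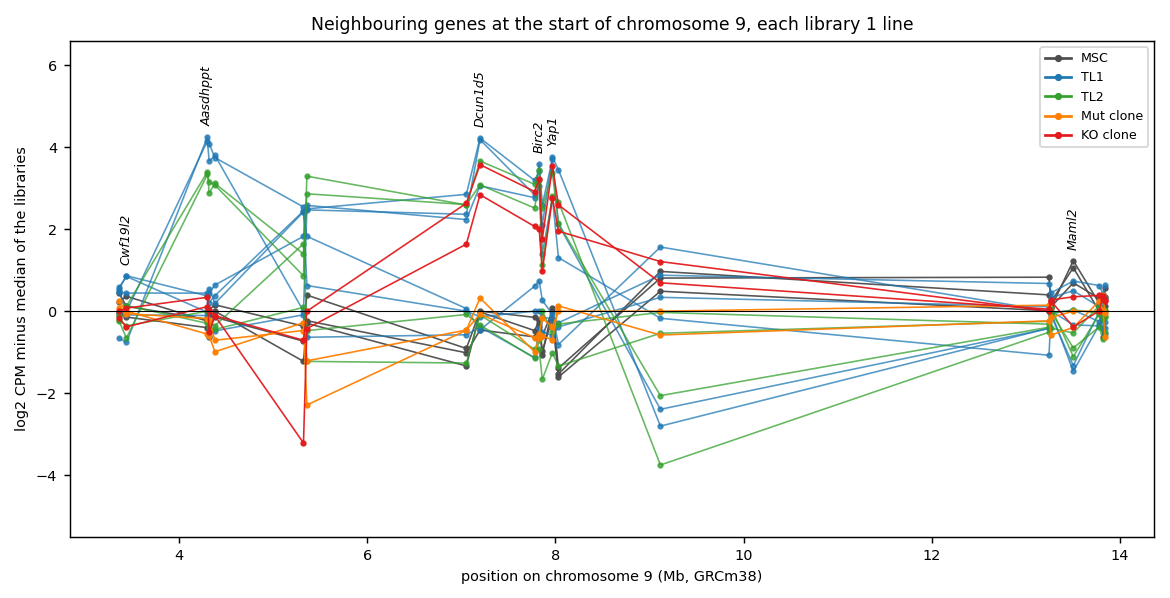
Log2 CPM minus the median of the 17 libraries for neighbouring genes at the start of chromosome 9, placed by the midpoint of each gene in megabases; each line is 1 library, coloured by group. Between Dcun1d5 and Yap1 the KO clones and several TL1 and TL2 lines lie above the MSC and Mut clone libraries.

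**Figure D4:**
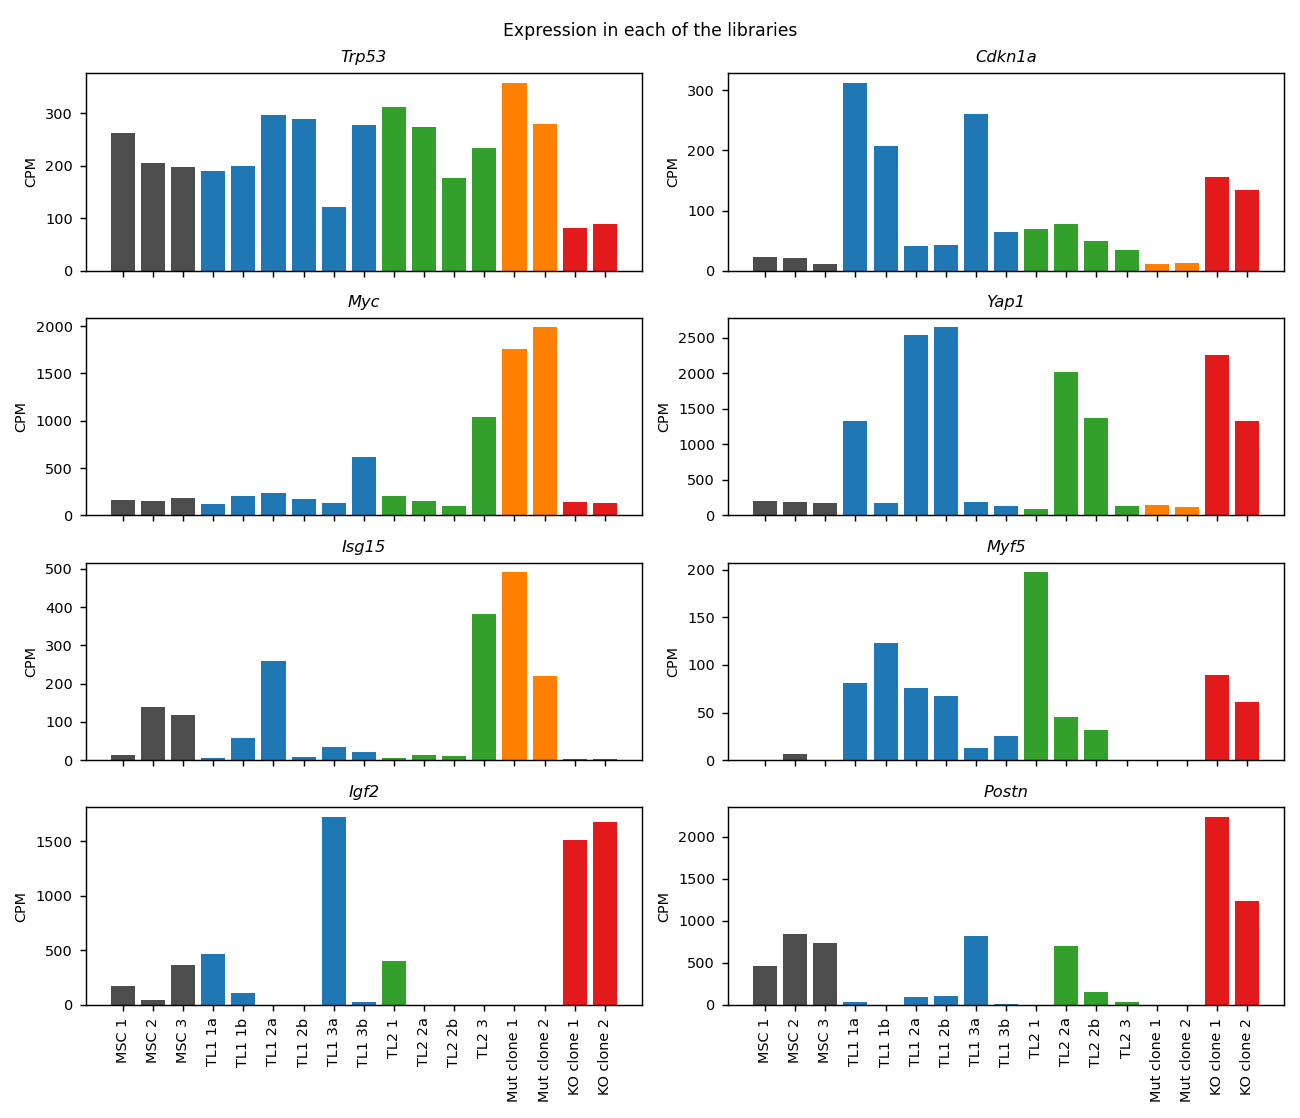
CPM of 8 genes in each of the 17 libraries, 1 bar per library, coloured by group. Trp53 is lowest in the KO clones at 80.8 and 89.6 CPM; Myc is highest in TL2 3 and both Mut clones, Isg15 in TL2 3, TL1 2a and both Mut clones, with MSC 2 and MSC 3 next at 138 and 119 CPM, and Yap1 in the tumour lines numbered 2, TL1 1a and both KO clones.

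The last comparison asked whether genes that differ between tumour lines and MSC moved back in the KO clones. The comparisons share no library. Of 12093 genes tested in both, 94 were higher in tumour lines and lower in KO clones, where 59.2 are expected of independent lists, and 105 were lower in tumour lines and higher in KO clones, where 59.3 are expected. Without Mut clone 1, Mut clone 2, KO clone 1 or KO clone 2 these counts were 53 and 67, 37 and 51, 45 and 74, and 39 and 56, and with the clones in a fit of all 17 libraries 35 and 44, each above the count expected of independent lists. In the same direction, 62 genes were higher in both (68.2 expected) and 28 lower in both (51.5 expected). Across all genes the log2 changes had a Spearman rho of -0.0572. Genes are not independent replicates. Igfbp6 rose by 5.11 in tumour lines and fell by 4.33 (SE 0.325) in KO clones, Fam83g fell by 7.62 (SE 0.724), Eps8, an actin regulator, rose by 3.09 (SE 0.338) and fell by 2.00 (SE 0.201), Kcnn4 rose by 3.89 (SE 0.553) and fell by 1.52 (SE 0.239), and Phex fell by 2.53 (SE 0.295). In the other direction, Tln2 fell by 1.93 (SE 0.281) and rose by 3.52 (SE 0.221), Pccb fell by 1.80 (SE 0.271) and rose by 1.96 (SE 0.285), Lox rose by 1.75 (SE 0.250), Plxdc2 fell by 5.96 (SE 0.976) and rose by 6.24 (SE 0.549), and Npr3, a natriuretic peptide receptor, fell by 4.17 (SE 0.405) in tumour lines and was at least 64.1-fold higher in the KO clones. The clone calls compare KO with Mut clones. In the KO clones Npr3 (5.27 and 9.32 CPM), Lox (1198 and 882 CPM), Kcnn4 and Phex stayed inside the range of the tumour lines. Their calls therefore do not show a move beyond the tumour lines towards MSC. Igfbp6, Fam83g, Eps8, Tln2, Pccb and, barely, Plxdc2 lay outside that range on the side of MSC, with Tln2 above every MSC library.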

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

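The counts of other splits of the samples were planned before the data were examined; the tests of the other explanations, including the limits set for them, were chosen after the results they concern had been seen.

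Between KO clones and Mut clones, 3200 genes were called, and the clones also differed in the tumour lines they resembled. A KO library rich in ribosomal precursor RNA as the whole cause is argued against by the fit without KO clone 2, which called 1375 genes. Different tumour lines of origin are a candidate explanation. Across genes, the KO minus Mut change was set against the deviation of the tumour lines of each number. Spearman rho was -0.385 for the lines numbered 3, 0.304 for those numbered 2 and 0.146 for those numbered 1. Of the called genes, 27.0% went in the direction of the lines numbered 3, 68.9% in that of the lines numbered 2 and 58.7% in that of the lines numbered 1. The deviations were taken from the mean over the numbers and cancel out for each gene. The values are therefore not independent of each other. The lines numbered 3 also include TL1 3a, the tumour line least like the Mut clones. Loss of mutant p53 alone cannot be told apart from origin with the 2 clones on each side and no line of origin in the labels: the 12 genes of the chromosome 9 run were higher in KO clones by a median of 1.98 on the log2 scale, mostly from Dync2h1 onwards, but genes of this stretch were as high in tumour lines that kept the mutant gene. Both stay open for the other genes.

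Runs of neighbouring genes lay above the other libraries in some tumour lines, such as 94 genes on chromosome 8 (92827290 to 107588482) in TL2 1 and in part in TL1 1b, 11 genes on chromosome 6 (17065149 to 24664995) with Met and Cav1 in TL1 3a and within a longer run in TL1 1b, and the run on chromosome 9. Chance order of genes is argued against for the runs as a set: 10 of the 17 libraries had a window of 9 genes above the highest of 100 shuffled orders, and 0 of the 100 shuffled orders put as many libraries above the others, the most being 1. It is not settled for each run, since some barely passed, such as that on chromosome 15 in TL2 2a (0.928 against 0.857). Gain of a chromosome segment may account for the runs, but it cannot be told apart from shared regulation here: over these 3 segments and the libraries with a run there, the share of genes more than 2-fold above the median library went from 50% in KO clone 2 and 58.3% in KO clone 1 (chromosome 9) and 64.9% in TL1 1b (chromosome 8) to 100%, and that of the genes beside them reached 40% in TL1 1b (chromosome 6), shares fixed in part because the ends of the segments were set by such genes, and copy number was not measured. The gene filter and the threshold were changed after a first scan of 12407 genes had been seen, which returned 11 runs in 6 libraries, among them clusters of related genes such as the Oas genes on chromosome 5, the Igf2 region on chromosome 7 and the muscle myosin genes on chromosome 11. The scan used here, over 10001 genes counted at 1 CPM or more in every library, returned 22 runs in 10 libraries, and no other explanation was tested.

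There were 11 genes at 5 CPM or more in every MSC library and below 0.5 CPM in every tumour line (Aldh1a2, Bmp5, Col15a1, Dscam, Fam213b, Hoxb2, Kcne4, Pitx1, Ppfibp2, Rps4y2 and Srpx), beside 1, Fmnl1, with the reverse pattern. Blood cells in the MSC cultures are argued against, since such cells bring all their abundant transcripts, while Ptprc, a marker of all blood cells, was at 0.139 CPM in MSC, the most abundant marker Lyn was at 17.3 CPM against 11.6 CPM in tumour lines, and the macrophage and haematopoietic list had a median log2 change of -0.112. Another body region of origin cannot be told apart either: the 9 tested Hox genes of paralogue groups 9 to 13 had a median of -0.0515 but went both ways, and Hoxc12 of these fell (log2 change -4.73, adjusted p = 0.0142 by edgeR). Culture medium and agar coating cannot be told apart from the origin in a tumour, since no tumour line was grown like MSC; 100% of the 11 genes were below 0.5 CPM also in the 4 clone libraries, which the labels' protocols place in the medium of the tumour lines. A change that came with tumour formation stays open as well.

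For tumour lines against MSC, a fit with all tumour lines as 1 group called 1357 genes, and 1 of 100 drawn splits of the 13 libraries into 3 and 10 gave as many, the real one. This argues against a grouping by chance but cannot exclude it, since only 100 of 286 possible splits were drawn. The splits also treat libraries as exchangeable. Lines of a number resemble each other, and the labels do not say that the MSC libraries came from separate cultures. The highest of the other splits, TL2 1, TL1 2a and TL1 2b against the rest, called 744. For TL2 against TL1 the real count was 0, which 100 of 100 splits of the 10 tumour lines must reach, so the splits decide nothing about it. The highest other split, TL1 1b, TL1 3a, TL1 3b and TL2 3 against the rest, called 318, which points to a structure of the samples other than generation. Among the 28 drawn splits that part the numbers as the real one does, the highest called 0.

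Of 206 groups of values in TL1 and TL2 examined for a library far from the others, 19 had one. The limit of 1 in 20 would give about 10.3 by chance for continuous values without ties. A group with 0 in all libraries but 1 passes the limit whatever its value, as for Adipoq, Srpx, Hoxb3, Ibsp and Kit. These numbers therefore do not show an excess over chance. All values are CPM, with the range of the other libraries of the group. In TL1, Cdh11 was at 215 in TL1 3a (others 3.07 to 13.4) and Fbn2 at 6.23 in the same line (0.0668 to 0.299). Slc38a4 was at 33.5 in TL1 2b (0.373 to 1.56), and Ier3 at 86.0 in TL1 2b (147 to 187). In TL1 3b, Ccl9 was at 8.89 (1.27 to 2.25), Higd1a at 64.6 (at most 39.6 in the others), Ndn at 0.672 (0 to 0.0692) and Pamr1 at 0.598 (0 to 0.0749). In TL1 1b, Pim3 was at 189 (101 to 124), Ccl8 at 0.195 (2.10 to 4.26), and Adipoq and Srpx both at 0.130, with 0 in the others. Hoxb3 was at 0.0751 in TL1 2b and 0 in the others. In TL2, Lox was at 1341 in TL2 2a (247 to 296), Cdh11 at 1.18 in TL2 1 (3.82 to 4.70), Npr3 at 4.27 in TL2 1 (at least 13.3 in the others), Eya2 at 0 in TL2 2b (0.129 to 0.131), Ibsp at 0.350 in TL2 2b (0 in the others) and Kit at 0.0657 in TL2 1 (0 in the others). Values below 1 CPM rest on few counts.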

How the results depend on the processing

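The fits without Rn45s, the fit of the 10 tumour lines alone and the list tests with the block by an estimated correlation and by fry were chosen after the data were seen; the other alternatives were planned. No gene that is named and called changed direction under an alternative run. For the genes named in tumour lines against MSC, 2817 of 3196 values stayed on their side of the threshold, 362 lost the call and 17 gained it; for the clones 1786 of 2039 stayed and 253 lost it; for TL2 against TL1 all 234 stayed. Where a cause is not given by fewer libraries, a stricter threshold or the pooled spread, the cause was not tested. Depth limits mainly genes with few counts in a group, whose changes are given as bounds or ratios.

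Tumour lines against MSC, given as higher and lower: 98 and 253 at an adjusted p under 0.01, 1164 and 1109 with DESeq2, and 1995 and 2344 with limma-voom. The fit of TL1 only called 356 and 415 and that of TL2 only 190 and 412. Without the libraries numbered 1 it was 32 and 125, without those numbered 2 it was 155 and 262, and without those numbered 3 it was 161 and 511. Leaving out single libraries gave 75 to 682 higher and 229 to 850 lower; both lowest values came without MSC 3, when 75 of the 512 and 226 of the 635 genes remained called. With the number as a block, 718 and 968 genes were called and 1 list, LIF and STAT3 targets, was lost. With the block, an estimated correlation called adipogenic, Hox, imprinted growth and also chondrogenic genes. In that fit, fry also called endothelial and epithelial markers, but no longer apoptosis genes. Whether the numbers pair MSC with tumour lines is not settled by the correlation of deviations, which was weak. It was 0.109, 0.00801 and 0.180 within the numbers 1, 2 and 3, against at most 0.0444, 0.0625 and -0.0459 with another number.

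For TL2 against TL1, DESeq2 called 3 genes and every other alternative 0; the block changed no call other than the 3 lists given with the comparison. For the clones, 512 and 308 were called with all 17 libraries in 1 fit and 738 and 454 at an adjusted p under 0.01; leaving out 1 clone gave 796 to 1016 higher and 502 to 753 lower, with the lone clone assumed to vary like the other group. The overlap of tumour lines with clones was 35 and 44 genes with the clones in the fit of all 17 libraries, 253 and 205 with DESeq2, and 37 to 53 and 51 to 74 with 1 clone left out, against 94 and 105; each count lay above the one expected of independent lists. The Trp53 difference kept its direction and its call under the alternatives run.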

Other observations

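The genes of this part were chosen after their values were seen, and no explanation was tested. Myod1, which commits cells to muscle, was at 7.55 to 572 CPM in 9 of the 10 tumour lines, at 0.129 CPM in TL2 3, at 0 and 0.159 CPM in the Mut clones and at 327 and 332 CPM in the KO clones. In MSC it was at 18.2, 4.68 and 0.456 CPM. Cdh15, the cadherin of muscle precursors, was at 46.2 to 394 CPM in these 9 lines, 1.09 CPM in TL2 3, 0.145 and 0.318 CPM in the Mut clones and 1161 and 1127 CPM in the KO clones. Acta1, skeletal muscle actin, was at 486 CPM in TL1 3a, below 2 CPM in TL1 1b, TL2 1, TL2 3 and the Mut clones, and at 1110 and 1533 CPM in the KO clones. Myh3, embryonic myosin, was at 78.3 CPM in TL1 3a, 0.130 CPM in TL1 1b, 0.131 CPM in TL2 1, and 225 and 290 CPM in the KO clones.

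The imprinted neighbours Igf2 and H19, of which the former is expressed from the paternal and the latter from the maternal chromosome, were both present in MSC, with Igf2 at 47.8 to 364 CPM and H19 at 205 to 450 CPM. No tumour line or clone had both above 2 CPM. In the 4 lines numbered 2, H19 was at 226 to 5019 CPM and Igf2 at 0.259 to 0.868 CPM. In the 3 lines numbered 1, Igf2 was at 109 to 465 CPM and H19 at 0.131 to 0.674 CPM, and TL1 3a had 1725 CPM of Igf2 and 0.554 CPM of H19. The KO clones had Igf2 at 1517 and 1675 CPM and H19 at 0.708 and 0.876 CPM, while TL2 3 and the Mut clones had both below 2 CPM. Myc was at 1042 CPM in TL2 3 and 1762 and 1987 CPM in the Mut clones, its neighbour Pvt1 at 487, 514 and 675 CPM, and Fam84b, on the other side of Myc on chromosome 15, at 964, 1161 and 1835 CPM. In TL1 3b, Myc was at 620 and Pvt1 at 142 CPM while Fam84b was at 4.78 CPM.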
